A study of Mus musculus with 12 samples.

How the data were processed

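Bulk RNA-seq was measured on progenitor cells sorted from the bone marrow of female C57Bl/6J mice, a common inbred laboratory strain. The 12 libraries cover 3 cell types with 4 libraries each: lymphoid-primed multipotent progenitors (LMPP), common lymphoid progenitors (CLP) and granulocyte-monocyte progenitors (GMP). The sample titles place 2 libraries of each type in each of 2 batches. Per the labels, marrow cells carrying mature lineage markers (CD3e, CD11b, B220, Gr-1 and TER-119) were depleted. The types were gated on surface proteins, with high Flk2 with Sca1, cKit and CD34 for LMPP, IL7Ra and Flk2 with low Sca1 and low cKit for CLP, and CD34 and the Fc gamma receptor on Sca1-negative cKit-positive cells for GMP. The protocol text describes single-cell work on LMPP, so the amount of RNA behind each bulk library and the age of the donors are not given in the sources used here. Nothing in the labels says that the libraries of a type came from separate animals, so p-values measure only the spread between these samples, which may be technical.

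The deposited table holds TPM, transcript abundance normalized to a fixed library total, for 38924 Ensembl gene IDs, and TPM values are relative to the total of each library, which came to between 999999 and 1000001 in the table as deposited. Per the submitters' processing notes, the tools were Bowtie2 2.2.0, RSEM 1.2.12 and edgeR 3.10.0 with the mm10 genome build; the notes give neither their order nor their settings. RSEM assigns reads that match several transcripts by estimated shares, so genes with near copies (the haemoglobin, Ly6c, histocompatibility and Serpina3 genes, and pseudogenes such as Gm4759) have uncertain values. Whether the counting used strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart. TPM keeps no sequencing depth: the number of reads behind a value is unknown, and no counting interval or detection floor can be given. A value of 0 is therefore described only as listed at 0. Another 17 columns of the table are not matched to these samples by name and were used in no step.

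Gene symbols and coordinates were taken from the GENCODE annotation of mm10, matched on the Ensembl ID; 37607 IDs had a symbol. Genes with at least 1 TPM in at least 4 libraries were tested, 12718 in all, of which 193 had no symbol. Values were transformed as log2(TPM + 1), so a fold change is on that scale and understates the change of genes near 0. Each gene was fitted with limma 3.58.1 in R 4.3.3 on all 12 libraries, with the cell type and an additive batch term, leaving 8 residual degrees of freedom. The variance was moderated with a trend on mean expression, and p-values of each comparison were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. All adjusted p-values below are from limma, and all tests are two-sided.

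The gene lists, the comparisons, the design, the naming rule and most alternative settings were fixed before the data were examined. The 19 lists hold 438 entries, 437 of them matched, and cover the 3 lineages, the other cell types that a marrow sort can contain, cell cycle, metabolism, interferon and stress responses, and the gate genes; some genes stand in 2 lists. Each list was tested in each comparison with camera at a preset correlation of 0.01, adjusted over the 57 list tests, and again with a correlation estimated from the residuals. With the estimated correlation, the early lymphoid list in CLP against GMP was called (adjusted p = 0.0164) and the other 56 list tests were not. The direction of a list is that of the camera test; where the median or mean of its members differs in sign, this is said. Member counts are also given with p-values adjusted over the list alone.

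Named genes followed a fixed rule. For each comparison these were the 8 genes with the largest change in each direction among called genes with a mean of at least 10 TPM in the higher type and no overlap between the libraries of the 2 types. Up to 3 called members of each list with the largest change were added, to a limit of 30 names. For 4 libraries against 4, an arrangement without overlap has a chance of 0.0286 per gene. Gate genes are given in every type, except Ly76 (TER-119), the entry without a matched ID. Aldoa, Pgam1, Cox5a, Uqcrc1, Mki67, Cenpf and Txnip, the members behind counts of 5 or fewer, and the genes shown for single libraries were named after their values were seen.

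The position of LMPP between GMP and CLP was computed over called genes that differ between CLP and GMP by at least 2 on the log2 scale, as the LMPP value on an axis with GMP at 0 and CLP at 1. Overlaps between comparisons that share libraries were set against 50 simulations of unchanged groups, against independent lists, and against 4 splits of the shared libraries, each beside independent lists of the sizes called in it. The fit was tested on simulated data: with 100 genes changed 2-fold and 100 changed 4-fold, it recovered 30% and 75% in LMPP against CLP, 32% and 78% in LMPP against GMP, and 34% and 60% in CLP against GMP, with 4, 12 and 9 other genes called among the 12718. A simulated shift of the glycolysis list was called in 2 of 2 tests and no other list in 55 tests. The genes were simulated as independent of each other, so this cannot show how the preset correlation performs on these data. Every type was also simulated with the same spread and the same batch shift for a gene. In the data, 1091 genes changed between batches differently in CLP and LMPP. The counts of other genes called therefore do not measure the error in these data. The correlation estimated for the B lineage list was 0.732.

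The alternatives covered the pseudocount (0.1 and 5), the filter (none, and 5 TPM), scaling by median ratios or quantiles, removal of 391 mitochondrial and ribosomal RNA genes from the total, the batch term, the replicate number as a block, averaging of same-numbered libraries, fits of only the compared types, each batch alone, 3 variance or threshold settings of limma, and each library left out in turn. The alternatives added after seeing the data were leaving out both CLP libraries of batch 2, leaving out the pair of libraries richest in haemoglobin transcripts, a fit of type by batch means, removal of the most abundant ID without a symbol, and gate genes left out of every list but their own. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The values of 1 gene are not reported here, and it was left out of the outlier test.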

Results

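Transcript levels of 3 haematopoietic progenitor types from mouse bone marrow were compared in 12 libraries, 4 per type. LMPP are multipotent cells primed towards the lymphoid lineages, CLP give rise mainly to lymphocytes, and GMP give rise to granulocytes and monocytes. LMPP libraries listed 12576 ± 461 genes at 1 TPM or more (SD, n = 4), CLP libraries 11797 ± 434 and GMP libraries 11187 ± 120.2. Sequencing depth is unknown, because TPM values carry no read totals. Mitochondrial and ribosomal RNA genes held between 17.14% and 34.61% of the TPM of a library. Libraries of the same type correlated across genes at r between 0.924 and 0.982 within a batch. Across batches r was 0.954 to 0.959 for GMP, 0.902 to 0.92 for LMPP and 0.839 to 0.882 for CLP; genes are not independent replicates.

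The gate genes describe the sorted populations and are no finding between them. Il7r, the interleukin 7 receptor chain used to gate CLP, was at 93.8 ± 24.3 TPM in CLP (SD, n = 4), 8.12 ± 3.00 TPM in LMPP and 0.205 ± 0.121 TPM in GMP. Fcgr3, an Fc gamma receptor gene of the GMP gate, was at 151.7 ± 24.5 TPM in GMP, 10.3 ± 16.6 TPM in LMPP and 9.34 ± 17 TPM in CLP, and Fcgr2b at 34.4 ± 3.25, 7.87 ± 4.38 and 8.21 ± 7.98 TPM in the same order. Flt3, which encodes Flk2, was at 123 ± 23.9 TPM in LMPP and 3.17 ± 0.363 TPM in GMP. In CLP, Flt3 was at 138.28 and 146.13 TPM in batch 1 but at 8.91 and 16.98 TPM in batch 2, and Cd34 was at 111.33 and 163.76 TPM in batch 1 but at 16.96 and 14.85 TPM in batch 2. Cd34 averaged 319 ± 60.1 TPM in LMPP and 119 ± 19.1 TPM in GMP. Kit averaged 108 ± 20.4 TPM in LMPP, 27.6 ± 13.7 TPM in CLP and 62.6 ± 10.9 TPM in GMP. Ly6a, the gene of Sca1, averaged 119.6 ± 28.9, 24.3 ± 15.3 and 7.39 ± 2.35 TPM in the same order. Slamf1, the gene of CD150, was below the filter, with at most 0.61 TPM in any library. Of the depletion genes, Itgam (CD11b) ranged from 14.13 to 90.83 TPM in LMPP, 8.53 to 48.54 TPM in CLP and 15.24 to 17.62 TPM in GMP. Ly6g (Gr-1) was at 0 to 112.37, 0 to 46.28 and 0 TPM, and Cd3e at 0 to 3.18, 0 to 10.39 and 0 to 0.07 TPM, in the same order. Ptprc, whose B220 form was depleted, averaged 96.5 ± 27.1, 73.2 ± 9.34 and 34.5 ± 3.68 TPM.

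Transcripts of mature blood cells stood high in some libraries. Hbb-bs, an adult beta globin gene, stood at 16930 TPM in LMPP batch 2 replicate 1 and 7882 TPM in CLP batch 2 replicate 1, against 7.86 to 1401 TPM in the other 10 libraries. S100a8, a calcium-binding protein of neutrophils, stood at 5611 and 2749 TPM in the same libraries and at no more than 941 TPM elsewhere. These libraries are called haemoglobin-rich below.

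**Figure D1:**
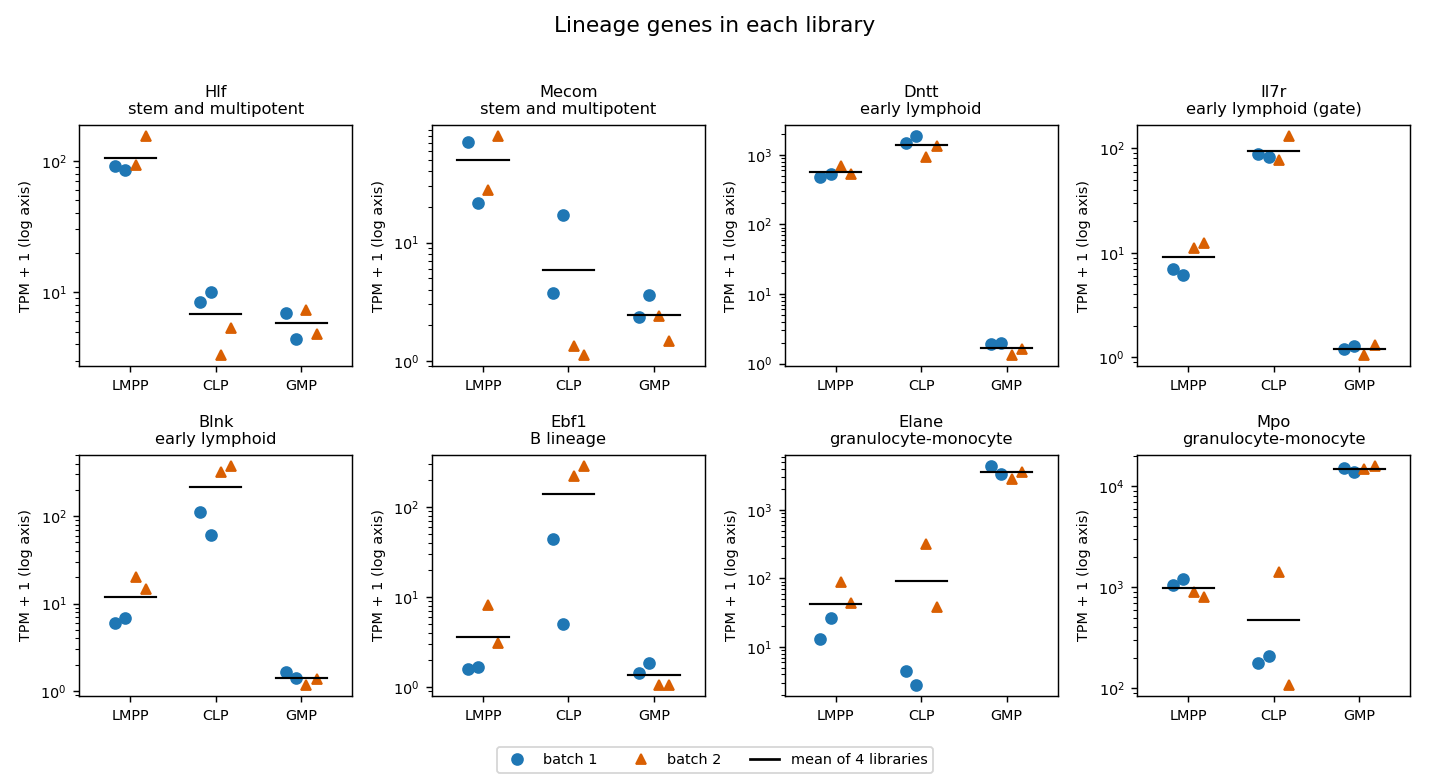
TPM + 1 on a log axis for 8 lineage genes in each of the 12 libraries, with circles for batch 1, triangles for batch 2 and a line at the mean of 4 libraries. Hlf and Mecom were highest in LMPP, Dntt, Il7r, Blnk and Ebf1 were highest in CLP, and Elane and Mpo were highest in GMP, where Mpo averaged 14920 TPM.

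LMPP expressed more of the stem and multipotent progenitor genes than CLP, and CLP expressed more of the early lymphoid and B lineage genes. Hlf, a transcription factor of haematopoietic stem cells (chromosome 11, 90336536 to 90390895 in mm10), averaged 105 ± 32.2 TPM in LMPP and 5.77 ± 3.04 TPM in CLP (SD, n = 4), a log2 difference of 4.05 (SE 0.333, limma adjusted p = 8.62e-05). Il7r, a gate gene (chromosome 15, 9505788 to 9530176), was lower in LMPP by a log2 difference of -3.41 (SE 0.231, limma adjusted p = 2.53e-05). Blnk, an adaptor of B cell receptor signalling (chromosome 19, 40928927 to 40994535), averaged 10.8 ± 6.73 TPM in LMPP and 217 ± 154 TPM in CLP, a log2 difference of -4.03 (SE 0.402, limma adjusted p = 0.000198). The stem and multipotent list had 17 of 26 members higher in LMPP and 0 lower, or 20 higher when adjusted over the list alone. An example was Mecom (3.78), a zinc finger regulator of stem cells, as a log2 difference. With the gate genes left out, 14 of 23 members were higher and the list stayed called (2.54e-10), but not with an estimated correlation (0.0959). The list was called upward at an adjusted p of 2.96e-12, with an adjusted p = 0.0956 with an estimated correlation.

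The early lymphoid list had 13 of 28 members lower in LMPP and 3 higher (14 lower and 3 higher when adjusted over the list alone). Lower members included Rag1 (-3.75), a subunit of the recombinase that joins antigen receptor genes, and Ly6d (-4.78), a surface protein of CLP turned towards the B lineage, in log2 differences; Cd27, Btla and Il2rg were the members higher in LMPP. The list was called downward at an adjusted p of 1.03e-10, with an adjusted p = 0.053 with an estimated correlation; with its gate genes left out, 12 of 26 members were lower and 3 higher (4.41e-10, and called at 0.033 with an estimated correlation). Rag1, Rag2, Igll1 and Vpreb1 stand in both the early lymphoid and the B lineage list. Over the CLP libraries Rag1 ranged from 6 to 64.6 TPM and Ly6d from 53.36 to 515.7 TPM. Between the batches of CLP, 10 of the 28 early lymphoid members were called higher in batch 2 and 7 lower (limma). Of the B lineage list, 12 of 18 members were lower in LMPP and 0 higher (18 lower when adjusted over the list alone). The B lineage list was called at an adjusted p of 5.4e-18, with an adjusted p = 0.159 with an estimated correlation. Its lower members included Igll1 (-5.69), Vpreb1 (-5.39) and Vpreb3 (-4.82), which encode surrogate light chain proteins of the pre-B cell receptor and a related assembly partner. In CLP, Igll1 stood at 314.7 and 0.13 TPM in batch 1 and at 2222 and 2677 TPM in batch 2. Without both CLP libraries of batch 2, 1 of 13 testable B lineage members was lower in LMPP, and without the haemoglobin-rich pair 3 of 13 were.

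Interferon response genes were higher in LMPP for 11 of 24 members and lower for 1, Ifi27l2a (14 higher and 1 lower when adjusted over the list alone). Ifitm1 (3.27), an antiviral membrane protein, and Oasl2 (2.62), of the oligoadenylate synthetase family, had log2 differences above 2, and the list was called at an adjusted p of 7.56e-05, with an adjusted p = 0.181 with an estimated correlation. Without both CLP libraries of batch 2, 7 of 24 members were higher. Immediate early genes, which respond within minutes to growth signals and to handling of cells, were higher for 6 of 16 members (8 when adjusted over the list alone), among them Ier3 (2.58), Fos (2.43) and Egr1 (2.33). The immediate early list was called at an adjusted p of 0.000474, with an adjusted p = 0.346 with an estimated correlation. Granulocyte-monocyte genes were higher in LMPP for 5 of 26 members (7 when adjusted over the list alone): Csf3r (2.79), the G-CSF receptor, Prtn3 (2.37), a granule protease, and Cebpa, Calr and Srgn. That list was called at an adjusted p of 0.00941, with an adjusted p = 0.554 with an estimated correlation, and the call ended without CLP batch 2 replicate 2 (0.201) or without LMPP batch 2 replicate 1 (0.108). The mast, basophil and eosinophil list, with Gata2 (2.37), Kit and Srgn higher among 14 members (3 when adjusted over the list alone), was called at 0.0271, with an adjusted p = 0.549 with an estimated correlation. The call ended without CLP batch 1 replicate 2 (0.0653), CLP batch 2 replicate 2 (0.254), LMPP batch 1 replicate 1 (0.0566) or LMPP batch 2 replicate 1 (0.199), and with the gate gene Kit left out of the list (0.109).

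Proliferation genes had a median log2 difference of -0.48 in LMPP against CLP, with Ccne1 and Ccne2, cyclins of the entry into DNA replication, lower among 32 members (2 when adjusted over the list alone). The list was called at an adjusted p of 2.22e-09, with an adjusted p = 0.245 with an estimated correlation, and without both CLP libraries of batch 2 its median was 0.06 and the call ended (0.46). Oxidative phosphorylation genes had a median of -0.22, with Cox5a, Cox8a and Atp5o lower among 24 members (4 lower when adjusted over the list alone). The oxidative phosphorylation list was called at 0.000135, with an adjusted p = 0.396 with an estimated correlation, and its median was 0.07 without both CLP libraries of batch 2 (0.405). The other 10 lists were not called. Of these, glycolysis had 2 of 16 members higher (Aldoa and Aldoc) and quiescence 4 of 15 higher and 1 lower (Txnip, Foxo3, Rbl2 and Tob1 against Cdkn1a). T, NK and innate lymphoid genes had 1 of 15 higher (Nkg7) and 2 lower (Tcf7 and Thy1). Dendritic cell genes had 3 of 15 higher (H2-Aa, H2-Ab1 and H2-Eb1), megakaryocyte and erythroid genes 4 of 21 (Itga2b, Car2, Nfe2 and Tfr2), mature neutrophil and macrophage genes 1 of 20 (Ccr2) and non-haematopoietic genes 1 of 5 (Emcn). Adjusted over the list alone, the counts higher and lower were 2 and 0 for glycolysis, 4 and 1 for quiescence, 2 and 2 for T and NK, and 3 and 1 for dendritic cell genes. The other such counts were 4 and 1 for megakaryocyte and erythroid, 1 and 0 for neutrophil, and 2 and 0 for non-haematopoietic genes. None of the 42 ribosomal protein genes or the 13 mitochondrially encoded genes was called in limma, and the ribosomal list had a median of 0.04 with a test pointing downward. Its direction depended on the setting: it was called upward under quantile normalization (median 0.17, 0.00264) and in batch 2 alone (0.166, 0.0175), and downward in batch 1 alone (-0.0861, 0.00921) and without both CLP libraries of batch 2 (-0.129, 0.00012). After median-ratio scaling it was not called (-0.09, 0.0576).

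Outside the lists, the largest increases in LMPP over CLP were in Gm25835 (4.78), a small nucleolar RNA gene, Muc13 (4.09), a membrane mucin, Mc5r (3.96), a melanocortin receptor, Rab38 (3.82), a small GTPase, Myct1 (3.76) and Serpina3g (3.60), a protease inhibitor with near copies, as log2 differences. The limma adjusted p was 0.0178 for Gm25835 and between 2.53e-05 and 0.000936 for the others. Gm25835 was listed at 0 in all 4 CLP libraries and at 12.73 to 66.53 TPM in LMPP. The largest decreases included Bfsp2 (-4.60), a filament protein best known from the lens, Tcrg-C1 (-4.11), a T cell receptor gamma constant gene, Slamf6 (-3.49), a lymphocyte surface receptor, and Socs2 (-3.20), an inhibitor of cytokine signalling. In all, 920 genes were higher and 356 lower in LMPP, 72.1% higher, of which 564 and 202 differed at least 2-fold. These counts used a single estimate of the spread per gene for all 3 types, GMP included. Libraries of the same batch correlated at r of 0.98 and 0.982 in GMP, 0.96 and 0.924 in CLP, and 0.963 and 0.929 in LMPP. With only LMPP and CLP in the fit, 370 genes were higher and 166 lower. After median-ratio scaling, which moved the median of all genes by -0.11 on the log2 scale, 595 were higher and 535 lower (52.7%), and quantile normalization gave 635 and 595 (51.6%). Within batch 2 alone, 456 genes were higher and 603 lower, without both CLP libraries of batch 2 655 and 233, and without the haemoglobin-rich pair 697 and 159. Leaving out LMPP batch 1 replicate 1, LMPP batch 2 replicate 1 or LMPP batch 2 replicate 3 gave 411, 570 and 469 higher and 195, 190 and 187 lower genes. Leaving out CLP batch 1 replicate 1 or CLP batch 2 replicate 2 gave 222 and 228 lower genes. The calls of Igll1, Vpreb1, Vpreb3, Prtn3, Ly6a and Gm25835 each ended without LMPP batch 2 replicate 3 (limma adjusted p 0.0529 to 0.109), and all but that of Gm25835 also ended without LMPP batch 2 replicate 1 (0.0515 to 0.0934). The calls of Igll1 and Vpreb3 ended without each library other than CLP batch 1 replicate 2 and 1 GMP library (0.0502 to 0.11). That of Vpreb1 ended without any CLP library but CLP batch 1 replicate 2 (0.0509 to 0.0555), and that of Prtn3 without CLP batch 1 replicate 1 (0.0745), CLP batch 2 replicate 2 (0.0813), LMPP batch 1 replicate 1 (0.0809) or LMPP batch 1 replicate 2 (0.0737). Tcf7, Thy1, Ccr2, Car2, Itga2b, Cox8a, Atp5o, Aldoa, Nkg7, Ccne1 and the class II genes, all behind small counts, also lost their calls without single libraries (0.0505 to 0.126). Within batch 1 alone the calls of the proliferation (0.214), oxidative phosphorylation (0.844) and interferon (0.119) lists ended, and within batch 2 alone that of the mast cell list (0.0986).

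GMP expressed most granulocyte-monocyte progenitor genes at higher levels than LMPP, which expressed more early lymphoid, multipotent and interferon response genes. Elane, the neutrophil elastase gene (chromosome 10, 79886247 to 79888215), averaged 41.7 ± 32.4 TPM in LMPP and 3564 ± 645 TPM in GMP (SD, n = 4), a log2 difference of -6.70 (SE 0.913, limma adjusted p = 0.000322). Mpo, the myeloperoxidase gene (chromosome 11, 87793581 to 87804413), averaged 992 ± 183 TPM in LMPP and 14920 ± 932 TPM in GMP, a log2 difference of -3.92 (SE 0.578, limma adjusted p = 0.000531). Dntt, which encodes the terminal transferase that adds nucleotides at antigen receptor joints (chromosome 19, 41029275 to 41059525), averaged 563 ± 93.2 TPM in LMPP and 0.693 ± 0.297 TPM in GMP, a log2 difference of 8.38 (SE 0.195, limma adjusted p = 1.45e-10). Of the granulocyte-monocyte list, 22 of 26 members were lower in LMPP and 0 higher (24 lower when adjusted over the list alone), with Ms4a3 (-5.41), a marker of the granulocyte-monocyte lineage, and Ly6c2 (-4.95), a monocyte surface protein with near copies, among them. The list was called at an adjusted p of 5.28e-19, with an adjusted p = 0.0956 with an estimated correlation.

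The early lymphoid list had 18 of 28 members higher in LMPP and 0 lower, the same count when adjusted over the list alone. Flt3, a gate gene (chromosome 5, 147330741 to 147400489), had a log2 difference of 4.88 and Gimap6 (4.94), a GTPase of lymphocytes, a similar one; the list was called at an adjusted p of 1.11e-08, with an adjusted p = 0.0733 with an estimated correlation. The stem and multipotent list had 20 of 26 members higher and 0 lower (24 when adjusted over the list alone), with Mecom (4.20), Hlf (4.17) and the gate gene Ly6a (3.86). The stem list was called at 7.07e-09, with an adjusted p = 0.153 with an estimated correlation. With the gate genes left out, 16 of 26 early lymphoid (1.76e-07) and 18 of 23 stem members (2.44e-08) were higher. Of the granulocyte-monocyte list, 21 of 25 members were then lower (3.25e-18). With an estimated correlation these adjusted p-values were 0.0626, 0.15 and 0.0959, and none of these lists was called. Interferon response genes were higher for 18 of 24 members and lower for 0 (20 and 1 when adjusted over the list alone), with Ifi44 (3.35), Rsad2 (2.99) and Oasl2 (2.79), all induced by interferon. The interferon list was called at 3.8e-06, with an adjusted p = 0.159 with an estimated correlation. Dendritic cell genes were higher for 9 of 15 members and lower for 1, Ly6c2 (10 and 1 when adjusted over the list alone), with the class II genes H2-Aa (4.00) and H2-Eb1 (3.58). Over the LMPP libraries H2-Aa ranged from 78.87 to 459.76 TPM and H2-Eb1 from 13.08 to 79.77 TPM. The summed TPM of the list was 1661.87 in LMPP batch 2 replicate 3, against 419.85 to 809.34 in the other LMPP libraries. The dendritic cell list was called at 0.00528, with an adjusted p = 0.312 with an estimated correlation. Quiescence genes were higher for 10 of 15 members and lower for 1, Gadd45b (11 and 1 when adjusted over the list alone), with Txnip (2.02), an inhibitor of thioredoxin. The quiescence list was called at 0.00125, with an adjusted p = 0.177 with an estimated correlation. Immediate early genes were higher for 8 of 16 members and lower for 0 (11 when adjusted over the list alone), with Egr1 (4.13). The immediate early list was called at 0.00441, with an adjusted p = 0.41 with an estimated correlation.

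Most called genes of oxidative phosphorylation and glycolysis were lower in LMPP than in GMP. Oxidative phosphorylation had 14 of 24 members lower and 0 higher (16 when adjusted over the list alone), such as Cox5a (-0.96), a subunit of cytochrome oxidase, and Uqcrc1 (-0.94), of complex III. The oxidative phosphorylation list was called at 5.93e-11, with an adjusted p = 0.177 with an estimated correlation. Glycolysis had 9 of 16 members lower and 2 higher, Pfkm and Aldoc (11 and 3 when adjusted over the list alone), such as Pgam1 (-1.41) and Aldoa (-1.26). The glycolysis list was called at 1.12e-05, with an adjusted p = 0.177 with an estimated correlation. Mast, basophil and eosinophil genes were lower for 4 of 14 members and higher for 1, Kit (6 and 1 when adjusted over the list alone): Hdc (-4.25), which makes histamine, Cpa3 (-3.15), a mast cell protease, Ms4a2 (-2.86), an IgE receptor chain, and Srgn. The mast cell list was called at 1.12e-05, with an adjusted p = 0.241 with an estimated correlation. Ribosomal protein genes, with Rpl8, Rpl18 and Rpl22 lower and Rpl5 higher among 42 (0 when adjusted over the list alone), had a median of -0.09. The ribosomal list was called at 0.00146, with an adjusted p = 0.619 with an estimated correlation. Under quantile normalization its median turned to 0.04 and the call ended (0.387). The B lineage list was not called, with Bank1 and Rag2 higher among 18 (1 when adjusted over the list alone). The T, NK and innate lymphoid list was not called either, with 6 of 15 higher, such as Tox (3.47), and Zbtb16 and Nkg7 lower (7 and 2 over the list alone). Nor was the proliferation list, with Cenpf higher and Mcm2 and Mcm5 lower among 32 (0 and 1 over the list alone). Neither were megakaryocyte and erythroid genes (1 of 21 higher, Car2 (3.97); 1 over the list alone), non-haematopoietic genes (2 of 5 higher, Emcn (3.17) and Pdgfrb; 2 over the list alone) and mitochondrially encoded genes (0 of 13 in limma). Mature neutrophil and macrophage genes had a median of 0.86 and a mean of 0.69 with a test pointing downward at an adjusted p of 0.468, and Vcam1 lower among 20 members (0 when adjusted over the list alone). Without the haemoglobin-rich pair their median was -0.03 and the list was called downward (0.00443, or 0.472 with an estimated correlation). Batch 1 alone also gave a downward call (5.92e-07, or 0.321), and batch 2 alone an upward one (median 3.74, 0.00986, or 0.682). Megakaryocyte and erythroid genes were called downward in batch 1 alone (median -0.44, 0.0419 at the preset correlation). The proliferation median and mean were 0.09 and 0.12 against a test pointing downward.

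Further genes with large increases in LMPP over GMP were Wfdc17 (5.94), a secreted protease inhibitor family gene, the ID ENSMUSG00000089944 (5.18), which had no symbol, Igkc (5.01), the kappa light chain constant region, and Gm4759 (4.33), an unprocessed pseudogene. Igkc reached 2669 TPM in the haemoglobin-rich LMPP library and 100.3 to 1105 TPM in the other LMPP libraries. Gm5111 was listed at 0 in all 4 GMP libraries and at 14.14 to 29.09 TPM in LMPP. Further decreases were in Fcgr3 (-4.89), Dmkn (-4.39) and Mt1 (-3.98), a metallothionein. In all, 2707 genes were higher and 969 lower in LMPP, 73.6% higher, of which 1543 and 395 differed at least 2-fold. Median-ratio scaling, which moved the median of all genes by -0.167 on the log2 scale, gave 1925 higher and 1613 lower (54.4%), and quantile normalization, with a shift of -0.276, gave 1552 and 1659 (48.3%). Without both CLP libraries of batch 2, 3793 genes were higher and 1480 lower, and within batch 2 alone 747 and 342. With only LMPP and GMP in the fit, 3729 were higher and 1454 lower, so the spread of CLP entered the main counts. Bank1, Cenpf, Mcm2, Rpl5, Rpl18, Vcam1, Pdgfrb and Kit, behind small counts, lost their calls without single libraries (0.0505 to 0.145). Within batch 1 alone the calls of the immediate early (0.061) and ribosomal (0.0903) lists ended.

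CLP and GMP stood furthest apart in the lymphoid and granule genes. Dntt averaged 1395 ± 382 TPM in CLP against 0.693 ± 0.297 TPM in GMP (SD, n = 4), a log2 difference of 9.66 (SE 0.195, limma adjusted p = 2.6e-11). Il7r had a log2 difference of 6.27 (SE 0.231, limma adjusted p = 1.86e-08). Elane was lower in CLP by a log2 difference of -7.48 (SE 0.913, limma adjusted p = 0.000146), and Ctsg (chromosome 14, 56099881 to 56102574), the cathepsin G gene of granules, by -6.75 (SE 0.836, limma adjusted p = 0.000157). The early lymphoid list had 25 of 28 members higher in CLP and 0 lower, the same when adjusted over the list alone, with Blnk (6.93) and Ly6d (6.41) among them. It was called at an adjusted p of 2.24e-18 and also with an estimated correlation (0.0164); with the gate genes left out, 23 of 26 members were higher (9.88e-17, and 0.0111). All 18 tested B lineage members were higher (18 when adjusted over the list alone), with Igll1 (5.94), Vpreb3 (5.82), Vpreb1 (5.73) and Ebf1 (5.54), a transcription factor that starts the B cell programme (chromosome 11, 44617317 to 45008091). The B lineage list was called at 5.59e-10, with an adjusted p = 0.247 with an estimated correlation. Ebf1 stood at 43.41 and 4 TPM in the CLP libraries of batch 1 and at 222 and 288 TPM in those of batch 2. Without both batch 2 libraries, 3 of 13 testable members were higher and the list stayed called (0.002), and without the haemoglobin-rich pair 10 of 13 were higher.

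The granulocyte-monocyte list had 24 of 26 members lower in CLP and 0 higher, the same when adjusted over the list alone, with Ms4a3 (-7.02), Prtn3 (-6.00) and Mpo (-5.76). The granulocyte-monocyte list was called at 8.13e-20, with an adjusted p = 0.0956 with an estimated correlation. Mast, basophil and eosinophil genes were lower for 9 of 14 members and higher for 0 (10 when adjusted over the list alone), with Hdc (-4.88), Cpa3 (-3.75) and Prg2 (-3.44), an eosinophil granule protein. The mast cell list was called at 1.06e-08, with an adjusted p = 0.159 with an estimated correlation. T, NK and innate lymphoid genes were higher for 11 of 15 members and lower for 2, Nkg7 (-3.27), a granule protein of killer cells, and Zbtb16 (12 and 2 when adjusted over the list alone). Tox (2.90) and Cd7 (2.78) were among the higher members. The T and NK list was called at 0.00235, with an adjusted p = 0.177 with an estimated correlation. Dendritic cell genes were higher for 10 of 15 members and lower for 1, Ly6c2 (10 and 1 when adjusted over the list alone), with Siglech (3.45), a lectin of plasmacytoid dendritic cells, and Irf4 (3.39). The dendritic cell list was called at 0.00185, with an adjusted p = 0.247 with an estimated correlation. Siglech stood at 70.18 and 26.51 TPM in batch 1 CLP and at 5.49 and 1.02 TPM in batch 2 CLP. Quiescence genes were higher for 11 of 15 members and lower for 1, Gadd45b (11 and 1 when adjusted over the list alone), with Cdkn1a (2.89), the p21 cell cycle inhibitor. The quiescence list was called at 0.00185, with an adjusted p = 0.181 with an estimated correlation, and not without both CLP libraries of batch 2 (0.0571). Glycolysis genes were lower for 12 of 16 members and higher for 0 (12 when adjusted over the list alone), with Aldoa (-2.31) and Pgam1 (-1.94). The glycolysis list was called at 4.54e-07, with an adjusted p = 0.159 with an estimated correlation.

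Proliferation genes were higher in CLP for 9 of 32 members and lower for 0 (11 when adjusted over the list alone), with Cenpf (2.00), a kinetochore protein, and Mki67 (1.37), the Ki-67 antigen. The proliferation list was called at 0.00551, with an adjusted p = 0.586 with an estimated correlation. Mki67 stood at 140.95 and 137.19 TPM in batch 1 CLP and at 633 and 718 TPM in batch 2 CLP. Without both batch 2 libraries 1 of 32 members was higher and the list call ended (0.911); without CLP batch 2 replicate 2 alone it also ended (0.0703). Oxidative phosphorylation genes had Cycs, Cyc1 and Uqcrc1 lower among 24 (2 when adjusted over the list alone) and a median of -0.32. The oxidative phosphorylation list was called at 7.56e-05, with an adjusted p = 0.396 with an estimated correlation. Ribosomal protein genes had Rpl4, Rpl8, Rpl22 and Rps2 lower among 42 (0 when adjusted over the list alone) and a median of -0.15. The ribosomal list was called at 0.00551, with an adjusted p = 0.695 with an estimated correlation; the call ended under quantile normalization (0.125), without CLP batch 2 replicate 1 (0.078) and without both CLP libraries of batch 2 (0.911). Interferon response genes, with 6 of 24 higher, led by Ifi27l2a (4.32), and Gbp3 and Cxcl10 lower (6 and 2 when adjusted over the list alone), were not called (0.0849). The stem and multipotent list had 4 of 26 higher (Mycn, Mllt3, Erg and Msi2) and 4 lower (Gata2, Kit, Tal1 and Lmo2; 5 and 4 over the list alone), with a median of 0.07 and a test pointing downward. Immediate early genes had 5 of 16 higher (Egr1, Nr4a1, Zfp36, Dnajb1 and Ddit4; 5 over the list alone) and non-haematopoietic genes 1 of 5 (Emcn; 1 over the list alone). Neither list was called, nor were the 13 mitochondrially encoded genes (0 in limma). Megakaryocyte and erythroid genes had a median of 1.17 with a test pointing downward, 1 of 21 higher (Car2) and 4 lower (Pf4, Itga2b, Nfe2 and Tfr2; 2 and 4 over the list alone). Mature neutrophil and macrophage genes had a median of 0.71 with a test pointing downward, and Vcam1, Cd68 and Ccr2 lower among 20 (2 over the list alone). Neither was called. Without the haemoglobin-rich pair these medians were 0.25 and -0.47, and the neutrophil list was called downward (0.00704, or 0.493 with an estimated correlation). The neutrophil list was also called downward in batch 1 alone (6.945e-07, or 0.321) and upward in batch 2 alone (median 3.56, 0.034, or 0.724). At the preset correlation, megakaryocyte and erythroid genes were called upward in batch 2 alone (median 2.98, 0.034). The stem list was called upward in batch 1 alone (median 0.68, 0.0168).

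Further large increases in CLP over GMP were in Bfsp2 (6.72), Arpp21 (5.83) and Sdc4 (5.77), a heparan sulphate proteoglycan, and further decreases in Fcgr3 (-5.30), Ly6c2 (-5.29) and Tfec (-5.16), a transcription factor of myeloid cells. In all, 1773 genes were higher and 1267 lower in CLP, 58.3% higher, of which 1000 and 702 differed at least 2-fold. Quantile normalization gave 1426 higher and 1588 lower genes (47.3%), and within batch 2 alone 1069 were higher and 703 lower. The call of Igll1 ended without CLP batch 1 replicate 1, CLP batch 2 replicate 2, GMP batch 2 replicate 1 or GMP batch 2 replicate 2 (limma adjusted p 0.0513 to 0.063). That of Prg2 ended without CLP batch 1 replicate 1, CLP batch 2 replicate 2, GMP batch 1 replicate 1 or GMP batch 1 replicate 2 (0.0544 to 0.0647). The call of Mki67 ended without GMP batch 2 replicate 1 (0.0551) or GMP batch 2 replicate 2 (0.055). Vcam1, Cd68, Pf4, Emcn, Car2, Egr1, Cyc1, Rpl4, Rpl22 and Rps2, behind small counts, also lost their calls without single libraries (0.0508 to 0.141). Within batch 1 alone the calls of the B lineage (0.0735), T and NK (0.117), quiescence (0.0903), proliferation (0.643) and ribosomal (0.703) lists ended, and within batch 2 alone that of oxidative phosphorylation (0.052).

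**Figure D2:**
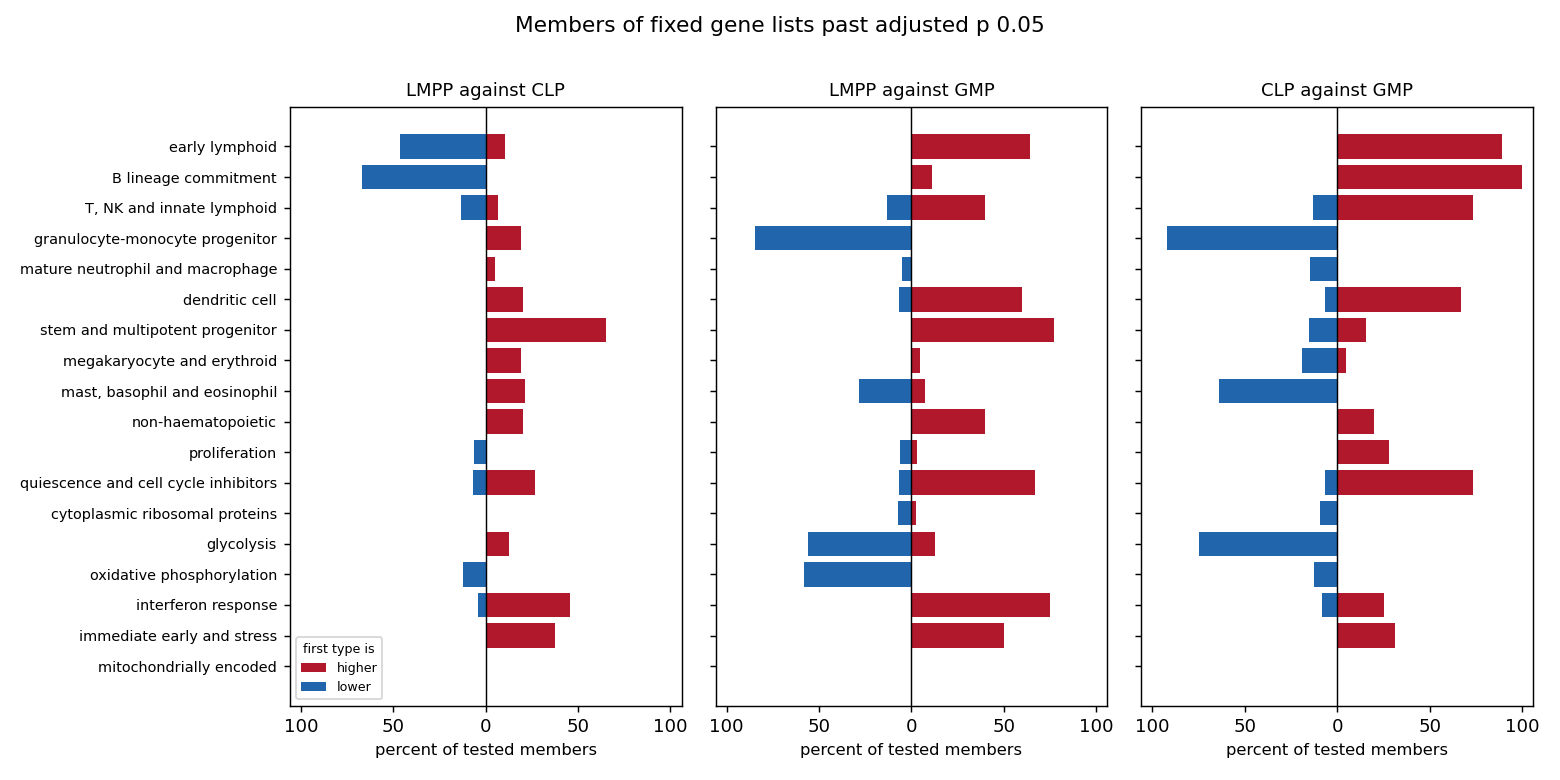
Percent of tested members of 18 gene lists that were called higher (red, to the right) or lower (blue, to the left) in the first type of each comparison, at a limma adjusted p under 0.05. The granulocyte-monocyte list had 22 of 26 members lower in LMPP and 24 of 26 lower in CLP than in GMP, and the stem and multipotent list had 17 of 26 members higher in LMPP than in CLP. The ribosomal median in LMPP against GMP turned sign under quantile normalization.

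Each type also had genes that differed from both other types in the same direction. GMP had 632 genes higher than both LMPP and CLP, among them Elane, Mpo and Ms4a3, and 1204 genes lower than both. LMPP had 491 genes higher than both, among them Hlf, Mecom and Oasl2, and 82 lower. CLP had 229 genes higher than both, among them Il7r, Blnk, Bfsp2 and Ebf1, and 280 lower. Median-ratio scaling gave 272 genes higher and 204 lower in LMPP, and quantile normalization 285 and 195, with 766 lower in GMP. Such overlaps share libraries between their comparisons. The 50 simulations with unchanged groups gave 0 genes in each class. No type differed from any other in them, so hardly any gene could be called. They cannot weigh overlaps of a type that differs from only 1 other type. Independent lists of the full sizes would share 195.8, 27.1, 49.6, 91.7, 96.5 and 377.4 genes for LMPP higher, LMPP lower, CLP higher, CLP lower, GMP higher and GMP lower. When the shared libraries were split between the comparisons, the same classes held on average 133, 14.8, 82.8, 126.5, 291.2 and 485.2 genes over 4 splits. Independent lists of the sizes called in those splits would share 36.2, 4.4, 12.5, 30.1, 24.4 and 90.3 genes on average, and in each class all 4 splits held more than that of their own lists. The ratio was 2.47 to 4.16 for LMPP, 3 to 6.91 for CLP and 5.02 to 12.69 for GMP. Both comparisons of a split came from 1 fit and shared the variance estimate and batch term of each gene. A ratio above 1 therefore does not by itself show genes particular to a type. Genes higher in LMPP came to 201 without LMPP batch 1 replicate 1, 212 without LMPP batch 2 replicate 3, 316 without LMPP batch 2 replicate 1 and 326 without GMP batch 1 replicate 1. Genes lower in LMPP came to 38 without LMPP batch 1 replicate 1, 43 without LMPP batch 2 replicate 1, and 49 without LMPP batch 2 replicate 3. They came to 48, 52 and 50 without GMP batch 1 replicate 1, GMP batch 1 replicate 2 and GMP batch 2 replicate 1. Genes higher in CLP came to 133 without CLP batch 1 replicate 1, and 132 without CLP batch 2 replicate 2. They came to 140, 144, 138 and 127 without LMPP batch 1 replicate 1, LMPP batch 1 replicate 2, LMPP batch 2 replicate 1 and LMPP batch 2 replicate 3. Genes lower in CLP came to 181 without GMP batch 2 replicate 1, 156 without LMPP batch 1 replicate 1, 182 without LMPP batch 1 replicate 2 and 186 without LMPP batch 2 replicate 1. Without the haemoglobin-rich pair, 310 genes were higher and 35 lower in LMPP and 116 higher in CLP, and without both CLP libraries of batch 2, 327 were higher in LMPP.

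Over 464 called genes that differed between CLP and GMP by at least 2 on the log2 scale, LMPP lay nearer to CLP than to GMP, at a median position of 0.651 on an axis with GMP at 0 and CLP at 1. The 4 LMPP libraries gave 0.663, 0.609, 0.593 and 0.706, a mean of 0.643 ± 0.0515 (SD, n = 4). The batch 2 libraries were first adjusted by the batch term common to all types, and the GMP and CLP means were held fixed. The SD therefore leaves out the spread of GMP and CLP. The 266 genes higher in CLP, such as Dntt and Blnk, had a median position of 0.683, and the 198 genes higher in GMP, such as Elane and Mpo, of 0.634. Of the 464 genes, 84.9% lay between both types, 12.1% beyond CLP and 3% beyond GMP. Within batch 2 alone the position was 0.527, close to midway between the types.

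**Figure D3:**
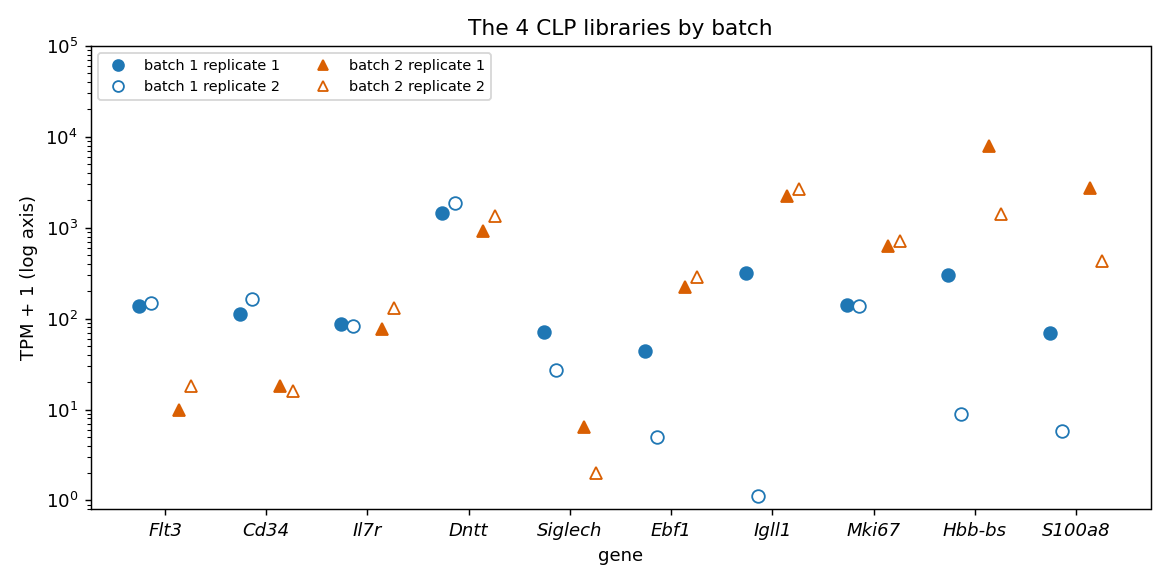
TPM + 1 on a log axis for 10 genes in the 4 CLP libraries, with circles for batch 1, triangles for batch 2, filled symbols for replicate 1 and open symbols for replicate 2. Flt3 stood at 138.28 and 146.13 TPM in batch 1 and at 8.91 and 16.98 TPM in batch 2, while Mki67 stood at 140.95 and 137.19 TPM in batch 1 and at 633 and 718 TPM in batch 2.

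CLP libraries differed between batches in more genes than those of the other types. Between batch 2 and batch 1, 4073 genes differed in CLP, 1046 in GMP and 586 in LMPP, with 2 libraries per batch and type (limma). The difference itself was tested: 1091 genes changed between batches differently in CLP and LMPP, 697 differently in CLP and GMP, and 2, Ube2c and Ighg2c, differently in LMPP and GMP. Of the 32 proliferation genes, 19 changed upward more in CLP than in LMPP and 0 less. Of the 26 stem and multipotent genes, 5 changed downward more in CLP than in LMPP and 1 upward. The summed TPM of 42 ribosomal protein genes was 92560 to 108600 in the 6 libraries of batch 1 and 47817 to 62037 in the 6 of batch 2.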

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

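Some values stood far from the other 3 libraries of their type. The gap, taken on log2(TPM + 1) for genes although TPM is printed, passed the critical share of the whole range in Dixon's test. This held in 25 of 256 groups of 4 values. Chance alone marks about 1 in 20 groups of normal values from 1 source. A gene listed at 0 in the other 3 libraries gives a gap of 1 at any level above 0, and each type spans 2 batches. The count is therefore no evidence of more outliers than chance gives. The tests of the single libraries, of the batch by type differences and of the haemoglobin pattern were chosen after the values were seen. The splits and the abundance and level tests of the LMPP to GMP counts were written before their results were seen. In the haemoglobin-rich CLP library, CLP batch 2 replicate 1, values far from the rest were those of Fcgr3 (34.76 TPM against 0.35 to 1.2, gap 0.851 of the range), Cpa3 (21.89 against 3.23 to 3.88, 0.915) and Ms4a2 (4.1 against 0, 1). In the same library Pgam1 (247 against 142 to 156, 0.832), Rsad2 (14.58 against 0.86 to 1.14, 0.934) and Tfec (11.38 against 0 to 0.36, 0.878) were far from the rest too. In CLP batch 2 replicate 2 they were Ly6a (2.24 TPM against 27.32 to 37.58, 0.875), Nkg7 (27.01 against 77.75 to 87.1, 0.902) and the number of genes above 0 (14409 against 16450 to 16612, 0.926). In LMPP batch 2 replicate 1, the haemoglobin-rich LMPP library, they were Rag1 (4 TPM against 0.51 to 0.68, 0.911) and Ly6c2 (149.88 against 28.02 to 33.58, 0.894). In LMPP batch 2 replicate 3 it was Hlf (152.99 against 84.45 to 91.25, 0.87). LMPP batch 1 replicate 1 held 8.48% of its TPM in the most abundant ID without a symbol, against 6.22% to 6.29% in the other LMPP libraries (0.969), and 8.93% in all IDs without a symbol, against 6.72% to 6.76% (0.982).

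In GMP batch 2 replicate 1, values far from the other GMP libraries were those of the small nucleolar RNA Gm25835 (93.02 TPM against 0, gap 1 of the range), Egr1 (2.55 against 0.93 to 1.06, 0.893), Wfdc17 (0.2 against 1.68 to 1.89, 0.914) and Mki67 (108.23 against 119.94 to 121.45, 0.891). In GMP batch 1 replicate 2 they were Ly6d (2.12 TPM against 0 to 0.14, 0.885), Pgam1 (465 against 710 to 720, 0.97), Cd7 (0.97 against 0, 1) and Ifi27l2a (6.25 against 2.63 to 3.04, 0.845). GMP batch 1 replicate 1 was alone above 0 for Tcrg-C1 (0.19 TPM, 1) and Tox (0.04 TPM, 1), and GMP batch 2 replicate 2 for Cd3e (0.07 TPM, 1).

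The change between batches differed between types by an interaction test chosen after seeing the data: 1091 genes between CLP and LMPP, 697 between CLP and GMP and 2 between LMPP and GMP (Ube2c and Ighg2c). A batch effect shared by every type would leave few such genes, and 1091 is against it as the whole cause. A shared part stays open: the batch differences correlated between types at r of 0.305 to 0.43 across genes, and the summed TPM of the ribosomal protein genes was lower in batch 2 in every type. Dilution of CLP by cells without early lymphoid transcripts could lower Flt3 (-3.42 in log2 from batch 1 to batch 2), and would lower the whole early lymphoid list about as much. That list had a median change of 0.267 (SD between members 2.3), with 16 of 28 members above 0. Set against the change in LMPP, its median was -0.573 (SD 2.08), with 5 members lower and 1 higher, and the list was called downward (0.00946, or 0.379 with an estimated correlation), against -3.82 for Flt3. Both medians lie above Flt3 by more than the SD, which is against dilution alone as the whole cause of its fall. Flt3 is a member of the list picked for its fall, and Rag1, Rag2, Igll1 and Vpreb1 stand in the B lineage list too. The test therefore cannot weigh dilution combined with a rise of B lineage transcripts, and a part stays open. A biological explanation, more B lineage committed cells in the batch 2 CLP sorts, may account for 16 of 18 B lineage members standing higher in both batch 2 libraries than in both of batch 1, and remains open, because the bulk values cannot tell more such cells from more transcripts per cell. Per the labels B220 was among the depleted markers, and depletion should remove B lineage cells that carry it. Set against the change in LMPP, the B lineage list had a median of 2.391, with 1 member called higher and 0 lower. It was called upward (camera adjusted p = 0.0198, or 0.713 with an estimated correlation). Set against the change in GMP, 2 members were called higher and 0 lower.

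The haemoglobin-rich pair, batch 2 replicate 1 of CLP and of LMPP, was weighed with tests chosen after the values were seen. RNA of mature blood cells may be the cause and remains open. In 18 of 20 mature neutrophil and macrophage members this pair was the highest among the 8 CLP and LMPP libraries, but the pair was chosen for its haemoglobin and neutrophil transcripts, so this count restates the choice. Lineage depletion should remove intact cells of that kind. A cause common to all libraries of batch 2, GMP included, is not likely, since in GMP the summed TPM of the megakaryocyte and erythroid list in batch 2 was 0.191 times that in batch 1. Expression by the sorted cells themselves is the biological explanation, and it remains open, because bulk libraries hold no value that separates it: both lists held 5.68% of the TPM in LMPP batch 2 replicate 1 and 2.68% in CLP batch 2 replicate 1, against 0.481% and 0.356% in the other CLP and LMPP libraries of batch 2, 0.0224% to 0.117% in those of batch 1 and 0.0402% to 0.309% in GMP. All 4 CLP and LMPP libraries of batch 2 thus stood above those of batch 1, so leaving out the pair removes only a part of this signal, and a cause common to CLP and LMPP of batch 2 stays open.

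The surplus of genes higher in LMPP than in GMP (73.6% of called genes) might come from the TPM scaling; of its 3 tests, the third was chosen after the result was seen, the others before. Without the 100 most abundant genes the share was 74.4% (2778 higher and 954 lower), against a few abundant genes as the cause. Among 6774 genes with a mean of at least 10 TPM it was 64.6% (1346 and 738), between both predictions, so more low-level genes detected in LMPP could account for a part. Under median-ratio scaling it was 54.4%, which cannot decide, because that scaling centres the genes by construction and RNA per cell was not measured; a broader transcriptome in LMPP, the biological explanation, may not be told apart from it.

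Regrouping the libraries tested whether grouping by chance could give the counts, with tests written before their results were seen. Of all 35 splits of 8 libraries into 4 and 4, only 1, the real one, gave a count as large. It gave 1276 called genes for LMPP against CLP (next highest 108), 3676 for LMPP against GMP (next 83) and 3040 for CLP against GMP (next 1). The next highest split for LMPP against GMP followed the batches, and that for LMPP against CLP put the batch 1 CLP libraries with the batch 2 LMPP libraries. In 100 splits of the 12 libraries into 3 groups, only the real one gave counts as large of genes higher or lower than in both other types (highest others 1 and 0 for LMPP, 1 and 1 for CLP, 4 and 45 for GMP). The other splits mixed the types, so type differences widened the spread within their groups and lowered these counts of genes. Such splits cannot say how many genes would be called without a type difference. For gene list calls, 22 of the 100 splits gave at least the real count of 31, with a median of 27 and a highest value of 39. Grouping by chance could give as many list calls, and the number of called lists is no evidence of differences between types.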

How the results depend on the processing

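Counts are given as higher, then lower; those of 1 type are against both other types, and counts not named stayed within 1.5 times. Median-ratio scaling gave 595 and 535 for LMPP against CLP, 1613 lower for LMPP against GMP, and 272 and 204 for LMPP. Quantile normalization gave 595 lower, then 1552 and 1659, then 285 and 195 for LMPP and 766 lower for GMP. The fit without a batch term gave 484 and 125 for LMPP against CLP, 540 lower for LMPP against GMP, 1079 higher for CLP against GMP, and 241 and 9 for LMPP, 97 and 151 for CLP and 396 and 701 for GMP. Only the compared types in the fit gave 370 and 166 for LMPP against CLP, 1454 lower for LMPP against GMP, 271 and 31 for LMPP and 128 and 114 for CLP; this fit gives no LMPP position. Batch 2 alone gave 456 and 603, 747 and 342, and 1069 and 703 in the 3 comparisons, 146 higher for LMPP, 382 and 179 for CLP, 160 and 372 for GMP, and a position of 0.527. Variance moderation without a trend gave 53 lower for LMPP. A test against a 2-fold change gave 27 and 11, 202 and 51, and 178 and 139 by its stricter threshold, and 12 and 0 for LMPP, 11 and 5 for CLP (Mc5r, Muc13, Krt18, B230118H07Rik and Rab38) and 42 and 80 for GMP.

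With the replicate number as a block, counts were 155 and 57 for LMPP against CLP, 1619 and 595 for LMPP against GMP, 91 and 10 for LMPP and 47 and 71 for CLP. Averaging same-numbered libraries gave 1133 higher for CLP against GMP, 41 lower for LMPP and 736 lower for GMP. The labels do not say that a number marks a shared animal. Deviations of same-numbered libraries correlated at -0.063 to 0.032 in the pairs computed, so the numbers were not taken to pair the libraries. Batch 2 LMPP, with replicates 1 and 3, was in none of these pairs. Replicate 1 of CLP and replicate 1 of LMPP in batch 2 shared high haemoglobin transcripts, so a pairing of these libraries stays open.

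Alternatives chosen after seeing the data moved some counts. Without both CLP libraries of batch 2, 233 genes were lower in LMPP than CLP, 1480 lower in LMPP than GMP and 327 higher in LMPP than both. Without the haemoglobin-rich pair the counts were 159 lower for LMPP against CLP, 310 and 35 for LMPP and 116 higher for CLP. Type by batch means gave 1600 and 733 for LMPP against CLP, 882 and 207 for LMPP and 476 and 516 for CLP. With 1 library left out in turn, ranges were 411 to 984 and 187 to 486 (LMPP against CLP), 1897 to 3293 and 660 to 1254 (LMPP against GMP), 1193 to 1796 and 882 to 1436 (CLP against GMP), 201 to 526 and 38 to 108 (LMPP), 127 to 321 and 156 to 372 (CLP), 423 to 744 and 820 to 1310 (GMP), 0.587 to 0.72 for the position and 29 to 33 list calls.

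Directions turned for few results, read from the list test at the preset correlation, so that a median may keep its sign. Medians are printed, with the adjusted p of the list at that correlation where it was called. Under quantile normalization the ribosomal list turned to 0.17 in LMPP against CLP (0.00264) and 0.0395 in LMPP against GMP. In batch 1 alone, megakaryocyte and erythroid genes turned to -0.44 in LMPP against GMP (0.0419), and in CLP against GMP stem genes to 0.68 (0.0168), ribosomal genes to 0.0751, proliferation genes to -0.0172 and Ube2c to -0.035. In batch 2 alone, the ribosomal list stood at 0.17 in LMPP against CLP (0.0175), neutrophil genes at 3.74 in LMPP against GMP (0.00986) and 3.56 in CLP against GMP (0.034), and megakaryocyte and erythroid genes at 2.98 in CLP against GMP (0.034). Proliferation genes in CLP against GMP had a median of 0.0294 without both CLP libraries of batch 2. A turn between values of which neither was called is counted as no change.

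List calls are counted here at the preset correlation. With the estimated correlation, only the early lymphoid list in CLP against GMP was called (camera adjusted p = 0.0164). Of 31 list calls at the preset correlation, at most 10 ended under any of the other alternatives (batch 1 alone). Of 173 calls of named genes, 8 ended under median-ratio scaling, 12 under quantile normalization, 43 without a batch term, 47 with the block, 100 against a 2-fold change and 10 to 30 with 1 library left out. With gate genes left out of the other lists, chosen after seeing the data, 30 lists were called. Ube2c was the only named gene whose direction turned. Except for the stricter threshold and the fits of only the compared types, the cause of moved counts was not tested. Those fits kept the genes and values of the main fit, and the median log2 differences of all genes stayed at 0.168, 0.244 and 0.086. Their counts therefore moved through the estimate of the spread and its degrees of freedom. TPM gives no depth, so the smallest detectable level is unknown.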

Other observations

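Xist, the long noncoding RNA that silences an X chromosome in female cells, averaged 461 ± 173 TPM in LMPP, 291 ± 18.3 TPM in CLP and 158 ± 42.8 TPM in GMP (SD, n = 4). It was higher in LMPP than in GMP (limma adjusted p = 0.000199) and in CLP than in GMP (limma adjusted p = 0.00486), and not called between LMPP and CLP (0.0696). Cox6a2, a muscle and plasmacytoid dendritic cell form of a cytochrome oxidase subunit, stood at 191.19 and 139.7 TPM in batch 1 CLP and at 1.39 and 2.56 TPM in batch 2 CLP, and at 5.37 to 7.65 TPM in LMPP. These genes were named after their values were seen.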
